A study of Homo sapiens with 6 samples.

How the data were processed

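Messenger RNA was measured by sequencing in 6 libraries of HO-1-N-1, a human cell line from an oral squamous cell carcinoma. Per the labels' protocols, the cells received an siRNA against Sam68 or a control siRNA with a lipid transfection reagent, poly(A) RNA was selected, and libraries were made with a kit whose name does not mark it as directional. The genome build was hg38, per the submitters' processing notes. The siRNA sequences, the time of harvest, the aligner, the counter and its strand setting are not given in the sources used here. The labels give 3 libraries to each group, numbered 1, 3 and 5 among the controls and 1, 2 and 3 among the Sam68 siRNA libraries. They do not say whether libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

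Per the file headers, the authors deposited raw read counts for 21462 genes, each with an Ensembl identifier and a chromosome span. Beside them stood RPKM values (reads scaled to transcript length and library size) and TPM values, both made by the authors. A signal per library, headed CPM, was also deposited; its columns sum to different totals, so a further factor had been applied, and it was not used in a test. The authors' comparison gave, per the file headers, a larger group mean, a fold change, a log2 fold change, a p-value, an FDR and a Bonferroni value per gene, with the test not named. The 5415 genes with no count in any library stand at 0 throughout that comparison and were read as not compared. For 2234 genes, none with more than 9 counts in total, the listed FDR was 0 and lay below the gene's own p-value, and it was read as not given.

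The counts were tested as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and the groups were compared by the quasi-likelihood F-test with robust estimation. Genes with a Benjamini-Hochberg adjusted p below 0.05 are called changed, and "rose" and "fell" are used of those only. Levels are CPM of the scaled library size, with the SD over 3 libraries. The SE of a log2 fold change is the one its F statistic implies. Levels of the histone, HLA, SAA and IFITM families, of MUC20 and of SMN2 are uncertain, since relatives with similar sequence could share reads. Levels of overlapping genes are uncertain as well, since the strand setting is not known; this holds for 52 of the 175 genes that the naming rule took.

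The groups, the tests, the 46 gene lists and the rule for naming genes were fixed before the data were examined. Lists with at least 3 tested genes were compared with all other tested genes by camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with adjustment over the 45 lists tested. The list of endothelial markers had 1 tested gene of 10 and was not tested. Camera with an estimated correlation was run beside it, as was fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes. The rule named the tested members of the STAR family and of the reported Sam68 target transcripts, the 12 largest rises and 12 largest falls among changed genes with a mean of at least 5 CPM and no overlap between groups, leaving out unnamed loci, and up to 4 changed members of each list by smallest p. Of these, the text gives a part, and some are not reported here.

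Alternatives fixed beforehand were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter, a stricter filter (at least 50 counts in 3 libraries), no robust estimation, the replicate number as a block, each library left out in turn, a test against a fold change of 1.5, limma-trend on log2 TPM or RPKM with a pseudocount of 1 or 0.1 and with or without a filter at 1, and for lists a prior count of 0.5. After the data were seen, the counts were also made without genes that hold either of 2 heptamers, and list members were counted without control replicate 5.

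For sequence, 1 protein-coding transcript per gene was taken from the basic set of GENCODE 29 on the same assembly, a principal one where annotated and among those the one with the longest 3' UTR. The log2 fold change, limited to 1.5 in either direction, was regressed on the presence of each heptamer with length, GC content and expression as covariates, over the 11950 genes with a 3' UTR of at least 50 bases. The z of each of 15710 heptamers found in at least 100 genes was set against the extremes over 1000 permutations of the genes. The coding sequences of 12226 genes were searched in the same way. Genes with no annotated 3' UTR were not searched. Python 3.11.15 was used with numpy 2.4.6 and pandas 2.3.3.

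The steps were tested on simulated data for the comparison of Sam68 siRNA with control siRNA, drawn from the real genes' means, dispersions and library sizes, with 200 genes changed and 12264 tested. The test called 28% of genes changed 1.25-fold, 76% of those changed 1.5-fold, 94% of those changed 2-fold and 96% of those changed 4-fold. Of 155 genes called, 8 had not been changed, and with no gene changed 1 was called. A list of 50 genes raised 1.25-fold was called and 0 of 44 unchanged lists were, with genes that varied independently, which real genes need not do. In the heptamer step, run on 11950 genes with permuted fold changes, a heptamer whose genes were given an added log2 change of 0.2 ranked first in 20 of 20 trials.

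The libraries held between 16099488 and 17336651 counts, and the common biological coefficient of variation was 9.14%. Intervals of a share of counts are Wilson 95% intervals and cover counting error only.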

Results

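The data were read counts per gene from poly(A) RNA of HO-1-N-1 oral squamous carcinoma cells given a control siRNA or an siRNA against Sam68, with 3 libraries each. Sam68, encoded by KHDRBS1, is an RNA-binding protein of the STAR family known to act in alternative splicing, and the comparison asks which genes differ in expression when it is knocked down. Control libraries 1, 3 and 5 held 16099488, 16798283 and 16175212 counts and Sam68 siRNA libraries 1, 2 and 3 held 17027515, 17336651 and 16402923. Between 14412 and 14590 genes had a count in a library. The first principal component of log2 CPM (42.4% of the variance) placed the controls between -24.7 and -13.0 and the Sam68 siRNA libraries between 16.3 and 17.9. The second (24.2%) placed control replicate 5 at -22.4 and controls 1 and 3 at 18.1 and 13.1. Transcripts of the mitochondrial genome took 2.27% of the counts in control replicate 5 (95% Wilson interval 2.26% to 2.28%), against 0.158% and 0.216% in controls 1 and 3 and 0.300%, 0.612% and 0.671% in the Sam68 siRNA libraries, with intervals no wider than 0.0145 percentage points. Every pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom of 6.38 between controls 1 and 3, of 39.7 and 33.4 between each of these and control replicate 5, and of up to 6.96 between the Sam68 siRNA libraries. Against the Sam68 siRNA libraries it was 16.9 to 22.1 for controls 1 and 3 and 38.4 to 44.7 for control replicate 5.

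KHDRBS1 mRNA (ENSG00000121774, hg38 chromosome 1, 32013868 to 32060850, plus strand) was lower in every Sam68 siRNA library. Controls 1, 3 and 5 held 227, 205 and 184 CPM and Sam68 siRNA libraries 1, 2 and 3 held 26.4, 31.0 and 28.8 CPM. The mean fell from 206 ± 21.3 CPM to 28.7 ± 2.29 CPM (SD, n = 3 each), a 7.15-fold lower level. The log2 fold change was -2.84 (SE 0.09), with an adjusted p of 1.56e-08 by edgeR's quasi-likelihood test. An exact two-sided permutation test of the 6 levels gave p = 0.1, the smallest that 3 against 3 allows. Of its relatives, KHDRBS2 had 0 counts in each library and KHDRBS3 between 1 and 5.

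**Figure D1:**
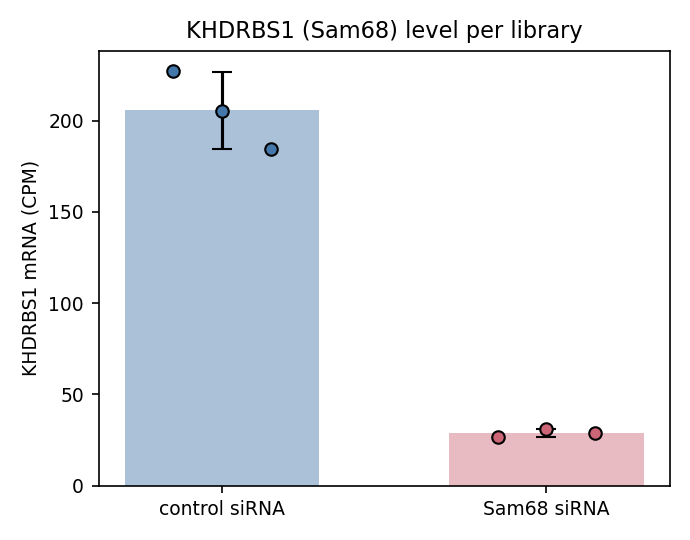
KHDRBS1 mRNA in CPM (y axis, from 0) in libraries given the control siRNA and the Sam68 siRNA (x axis). Bars are means of 3 libraries, error bars the SD and points the libraries; the Sam68 siRNA libraries lie at 26.4 to 31.0 CPM and the controls at 184 to 227 CPM.

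Among the largest falls after KHDRBS1 were genes for secreted and surface proteins. SPP1, which encodes the secreted phosphoprotein osteopontin, fell from 18.7 ± 3.79 to 3.20 ± 0.442 CPM (n = 3 each; log2 fold change -2.54, SE 0.17, adjusted p = 9.36e-06 by edgeR). VTCN1, the immune checkpoint ligand B7-H4, fell from 26.1 ± 3.83 to 5.89 ± 0.905 CPM, and OLFM4, a secreted glycoprotein of epithelia, from 192 ± 38.5 to 49.1 ± 3.13 CPM. COL1A1, a chain of collagen I, fell from 33.2 ± 1.23 to 9.87 ± 1.05 CPM and VIM, the intermediate filament protein vimentin, from 10.2 ± 3.89 to 3.74 ± 0.0919 CPM. Other falls among the 12 largest were those of BTBD1, from 103 ± 4.61 to 36.7 ± 2.63 CPM, and CCDC146, H1-2, H2AC6 and MUC20, with log2 fold changes of -1.80, -1.41, -1.34 and -1.33. CCDC146 overlaps GSAP on the other strand, which holds 132% of its counts, and its level is uncertain.

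Named rises were smaller than the largest falls. IFITM1, an interferon-inducible membrane protein, rose from 4.02 ± 0.978 to 9.32 ± 1.60 CPM (n = 3 each; log2 fold change 1.21, SE 0.19, adjusted p = 0.00139 by edgeR). THG1L, which adds a guanylate to histidine tRNA, rose from 8.99 ± 1.13 to 20.7 ± 1.77 CPM, and STEAP3, a ferrireductase, from 22.1 ± 1.82 to 48.5 ± 2.21 CPM. IL6ST, the gp130 receptor subunit of the interleukin 6 family, rose from 73.2 ± 3.87 to 141 ± 12.4 CPM, and EMP2 and HIPK3 rose by 0.94 and 0.93 in log2. RAB36, ISM1, TOP1MT and SLC22A4 rose by 0.93, 0.90, 0.90 and 0.89. SLC22A4 overlaps P4HA2 on the other strand, which holds 1090% of its counts, and is uncertain. The DDIT4 log2 fold change, for a stress-induced inhibitor of mTOR signalling, was 0.96 (adjusted p = 0.0145), and without Sam68 siRNA replicate 2 its adjusted p was 0.0515, the highest with 1 library left out (lowest 1.67e-06, without control replicate 5).

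In all, 1152 genes rose and 1206 fell of 12351 tested (19.1%), with median log2 fold changes of 0.36 and -0.37. Over 2-fold, 12 rose and 86 fell. The groups did not overlap in 4691 tested genes (38.0%, where chance gives 10%). The count of changed genes, 2358, was 1537, 1112 and 1195 without Sam68 siRNA replicates 1, 2 and 3, and 28 genes passed a test against a fold change of 1.5.

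The mRNAs of several of these genes held 1 of 2 heptamers that were singled out after the data were seen. GCAGTAC lay in the 3' UTR or coding sequence of 8 of the 12 largest rises under the naming rule, in 7 of them in the 3' UTR. Of 560 genes with GCAGTAC in the 3' UTR 30.2% rose and 5.0% fell, against 8.41% and 10.2% of genes without it. In THG1L it lay at chromosome 5, 157739731 to 157739737, and in STEAP3 at chromosome 2, 119263483 to 119263489 (both in exon 6). ACTGATT lay in 4 of the 12 largest falls, namely KHDRBS1, VTCN1 and H2AC6, in the 3' UTR, and SPP1, in the coding sequence, and H1-2 was not searched. It also lay in the 3' UTR of DDIT4 and IL6ST, which are among the largest rises. In KHDRBS1 it lay at chromosome 1, 32042668 to 32042674, in the 3' UTR (exon 9). Of 1646 genes with ACTGATT in the 3' UTR 15.1% fell and 6.93% rose, against 9.09% and 9.83% of genes without it. Among rises named later, GCAGTAC also lay in the 3' UTR of HYOU1, LAMP2 and TGFB2. It lay in the coding sequence of PLK1, SLC7A5, PTBP3, HNRNPUL1, COL6A1, TIMP3, SRPK1 and TNRC6A, and of PPL and ITGB2, which fell. GCAGTAC also lay in the 3' UTR of AGO3, which fell. Among falls named later, ACTGATT lay in the 3' UTR of CTSA, CRIM1, SRSF8, MAP2 and AGO3 and the coding sequence of BIRC3, MAP2 and AGO3. It also lay in ETV5, FOXM1, MYBL2, CDH3, P4HA1 and SRF, which rose.

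**Figure D2:**
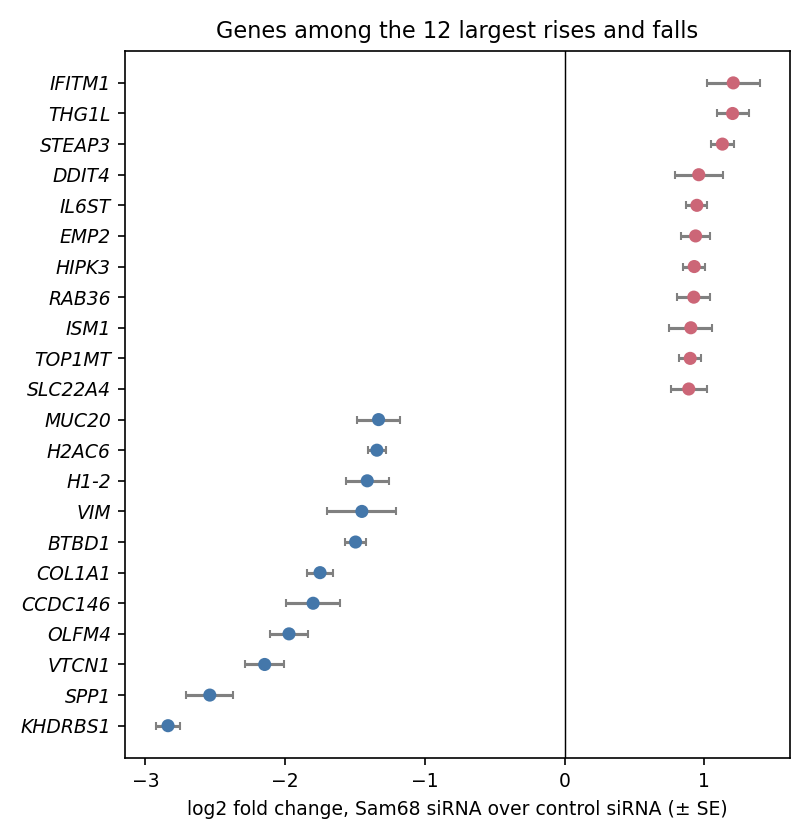
Log2 fold change of Sam68 siRNA over control siRNA (x axis) for 11 of the 12 largest rises and 11 of the 12 largest falls under the naming rule (y axis), 3 libraries per group. Points are edgeR estimates and bars ± SE; KHDRBS1 lies lowest at -2.84 and IFITM1 highest at 1.21.

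Genes of the cell division cycle were higher with the Sam68 siRNA. Of 54 G2/M cell cycle genes 25 rose, 0 fell and 29 were not called (37 rose adjusted over the list alone). FOXM1, a transcription factor of mitotic genes, rose from 61.1 ± 8.41 to 98.6 ± 5.65 CPM (n = 3 each), and the mitotic kinase PLK1, MYBL2 and KIF20A rose by 0.55, 0.60 and 0.68 in log2. FOXM1 and KIF20A overlap RHNO1 and CDC23 on the other strand, which hold 28.1% and 105% of their counts, and are uncertain. Of 44 G1/S cell cycle genes 18 rose, 0 fell and 26 were not called (31 rose and 1 fell adjusted over the list alone), with the replication licensing factor CDT1 at 0.42 and the helicase subunits MCM3 and MCM7 at 0.32 and 0.41. Of 39 DNA repair genes 16 rose, 1 fell and 22 were not called (20 and 1 adjusted over the list alone), with the exonuclease EXO1 at 0.60 and FANCG at 0.46. Camera placed these lists above other genes (adjusted p = 2.55e-11, 1.72e-08 and 2.33e-06). In the same order, the values were adjusted p = 0.494, 0.494 and 0.452 with an estimated correlation. Over all 6 libraries fry called neither cell cycle list (adjusted p = 0.0931 for G2/M and 0.0504 for G1/S). Without control replicate 5 fry called both (adjusted p = 0.00994 and 0.0319). Camera with an estimated correlation called neither there (adjusted p = 0.345 and 0.450). The G2/M list lay 0.46 below the mean of the 6 libraries in control replicate 5 (a log2 deviation of -0.462), and at -0.062 and -0.040 in controls 1 and 3. Without control replicate 5 the median log2 fold change of the G2/M cell cycle genes was 0.25, against 0.38 with it; 27 G2/M genes rose and 1 fell, 17 G1/S genes rose, and 13 repair genes rose and 1 fell. Without Sam68 siRNA replicates 1, 2 and 3, in that order, 16, 12 and 11 G2/M genes rose, 9, 8 and 11 G1/S genes and 9, 9 and 8 repair genes; of the repair genes 3, 0 and 0 fell.

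Replication-dependent histones, whose mRNAs mostly lack a poly(A) tail, were lower among the transcripts counted. Poly(A) RNA was selected, so their mRNAs without a tail were largely not measured. Of 7 tested (13 in the table) 0 rose, 6 fell and 1 was not called (7 fell adjusted over the list alone). H2AC6 fell from 69.8 ± 0.698 to 27.5 ± 0.605 CPM (n = 3 each), and H2BC5 and H2BC12 changed by -1.12 and -1.06 in log2, all uncertain as members of a gene family. Camera gave an adjusted p of 1.75e-06, and adjusted p = 0.452 with an estimated correlation. The list lay at 0.809 in control replicate 5, as a log2 deviation from the mean of the 6 libraries, and at 0.373 and 0.490 in controls 1 and 3, and without control replicate 5, 5 of the 7 fell.

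Genes of the ATF4 amino acid response were higher, 18 of 32 rising, 0 falling and 14 not called (23 rose and 1 fell adjusted over the list alone). SLC7A5, a transporter of large neutral amino acids, rose from 2414 ± 65.9 to 3487 ± 126 CPM (n = 3 each). Asparagine synthetase (ASNS) rose by 0.60, PCK2 by 0.62 and PHGDH, the first enzyme of serine synthesis, by 0.46 in log2. Camera gave an adjusted p of 2.67e-08, and adjusted p = 0.452 with an estimated correlation. The count was 18 without control replicate 5 as well.

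Of 77 cytosolic ribosomal proteins 18 rose, 0 fell and 59 were not called (19 rose adjusted over the list alone), with a median log2 fold change of 0.11. RPSA rose from 646 ± 35.8 to 812 ± 26.7 CPM (n = 3 each), and RPL12 and RPS2 rose by 0.45 and 0.29 in log2. Camera gave an adjusted p of 1.57e-06, and adjusted p = 0.494 with an estimated correlation. The count was 9 without control replicate 3 and 5, 3 and 5 without Sam68 siRNA replicates 1, 2 and 3. Of 29 hnRNP proteins, which bind nascent transcripts, 8 rose, 1 fell and 20 were not called (8 and 1 adjusted over the list alone), with PTBP3 at 0.55 and HNRNPUL1 (uncertain, overlapping TGFB1) at 0.49. Camera gave an adjusted p of 0.00209, and adjusted p = 0.452 with an estimated correlation. The number of hnRNP genes that rose was 5 without control replicate 3, and 4, 3 and 5 without Sam68 siRNA replicates 1, 2 and 3; 0 fell without control replicate 1 or any single Sam68 siRNA library.

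In cholesterol biosynthesis 9 of 25 genes rose, 1 fell and 15 were not called (12 and 1 adjusted over the list alone). STARD4, a sterol carrier, rose from 24.2 ± 2.13 to 37.1 ± 1.22 CPM (n = 3 each; log2 fold change 0.62), and the synthase FDPS rose by 0.27 in log2. Against other genes the list had an adjusted p of 0.00691 by camera, and adjusted p = 0.464 with an estimated correlation. The fall in this list was not called without control replicate 3 or Sam68 siRNA replicates 2 and 3, and 2 fell without control replicate 5. In fatty acid synthesis and desaturation 7 of 18 rose, 2 fell and 9 were not called (8 and 3 adjusted over the list alone), ACSS2, ELOVL6 and ELOVL7 rising by 0.52, 0.47 and 0.62 and the desaturase SCD5 changing by -0.40. That list gave an adjusted p of 0.0411 by camera, and adjusted p = 0.452 with an estimated correlation. Without control replicate 1 its adjusted p was 0.126 and without Sam68 siRNA replicate 1 it was 0.0572 (lowest 0.0174, without control replicate 3); 1 gene fell, not 2, without any library but control replicate 1.

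Lower groups included the NRF2 oxidative stress response, of which 0 of 27 genes rose, 12 fell and 15 were not called (13 fell adjusted over the list alone). FTL, the ferritin light chain, fell from 1190 ± 124 to 812 ± 36.0 CPM (n = 3 each), and GCLC, an enzyme of glutathione synthesis, changed by -0.29 in log2. By camera its adjusted p was 0.00014, and adjusted p = 0.489 with an estimated correlation. The list lay at 0.349 in control replicate 5, as a log2 deviation from the mean of the 6 libraries, and at 0.068 and 0.060 in controls 1 and 3. Without control replicate 5, 10 genes fell, and without Sam68 siRNA replicates 1, 2 and 3, 5, 2 and 4 did.

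Of 33 lysosome and autophagy genes 1 rose, 12 fell and 20 were not called (1 and 13 adjusted over the list alone). The sialidase NEU1 fell from 124 ± 4.51 to 90.7 ± 5.01 CPM (n = 3 each), CTSA and MAP1LC3A changed by -0.35 and -0.44 in log2, and LAMP2 rose by 0.38. The camera test gave an adjusted p of 0.00382, and adjusted p = 0.452 with an estimated correlation. The number that fell was 7, 5 and 4 without Sam68 siRNA replicates 1, 2 and 3, and 2 rose without control replicate 1. Of 22 YAP/TEAD targets 1 rose, 8 fell and 13 were not called (1 and 8 adjusted over the list alone). CCN1, a secreted matricellular protein, fell from 510 ± 115 to 216 ± 17.2 CPM, CRIM1 (uncertain, overlapping FEZ2) and ANKRD1 changed by -0.46 and -0.74 in log2, and TGFB2 rose by 0.35. Against other genes the list had an adjusted p of 0.006 by camera, and adjusted p = 0.452 with an estimated correlation.

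Of 19 immediate early genes, which respond first to growth factors and stress, 1 rose, 3 fell and 15 were not called (1 and 3 adjusted over the list alone). CCN1, MCL1 and IER5 fell, by log2 fold changes of -1.24, -0.37 and -0.32. The SRF log2 fold change was 0.27 (adjusted p = 0.015), and without Sam68 siRNA replicates 1 and 2 its adjusted p was 0.0642 and 0.0638 (lowest 0.00806, without control replicate 5). Camera gave the list an adjusted p of 0.0397, and adjusted p = 0.74 with an estimated correlation. These immediate early genes lay at 1.21 in control replicate 5, as a mean log2 deviation from the 6 libraries, and at -0.231 and -0.114 in controls 1 and 3. Without control replicate 5 the list's adjusted p was 0.256 and its median 0.02, with 2 genes rising and 8 falling, and without Sam68 siRNA replicate 1 its adjusted p was 0.0569 (lowest 0.0028, without control replicate 1).

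**Figure D3:**
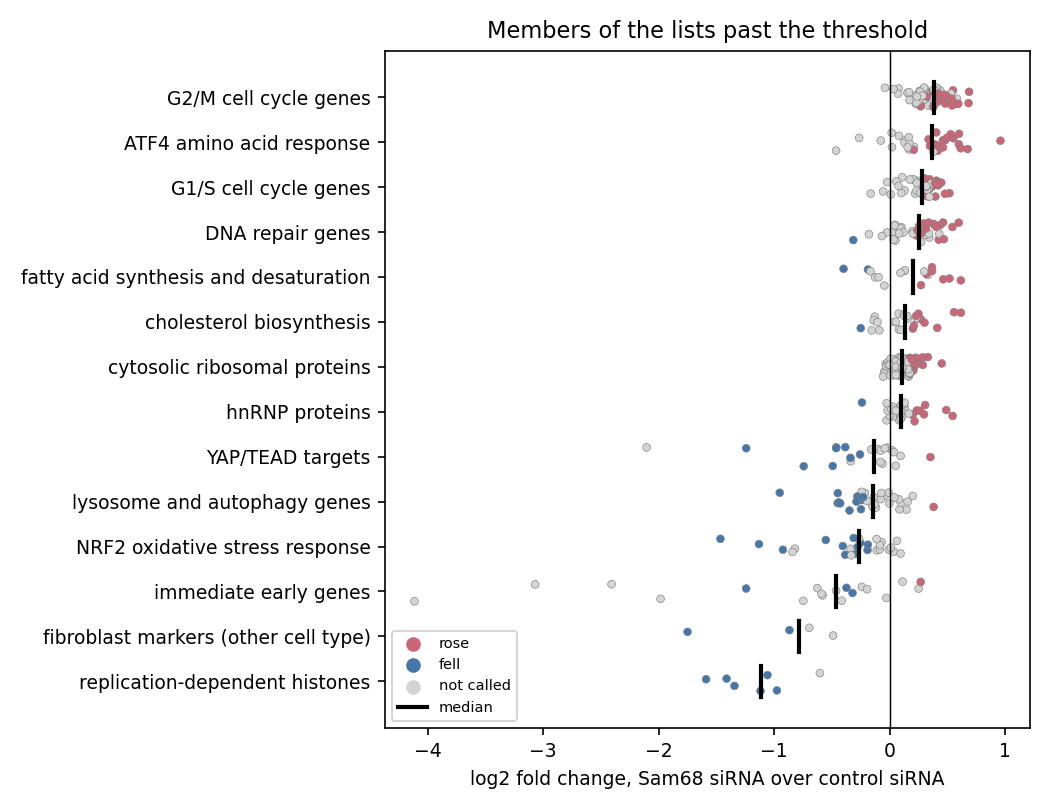
Log2 fold change of Sam68 siRNA over control siRNA (x axis) for each tested member of the 14 lists past the camera threshold (y axis). Coloured points passed the test for a gene, grey points did not, and bars are medians, from -1.12 for histones to 0.38 for G2/M cell cycle genes.

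**Figure D4:**
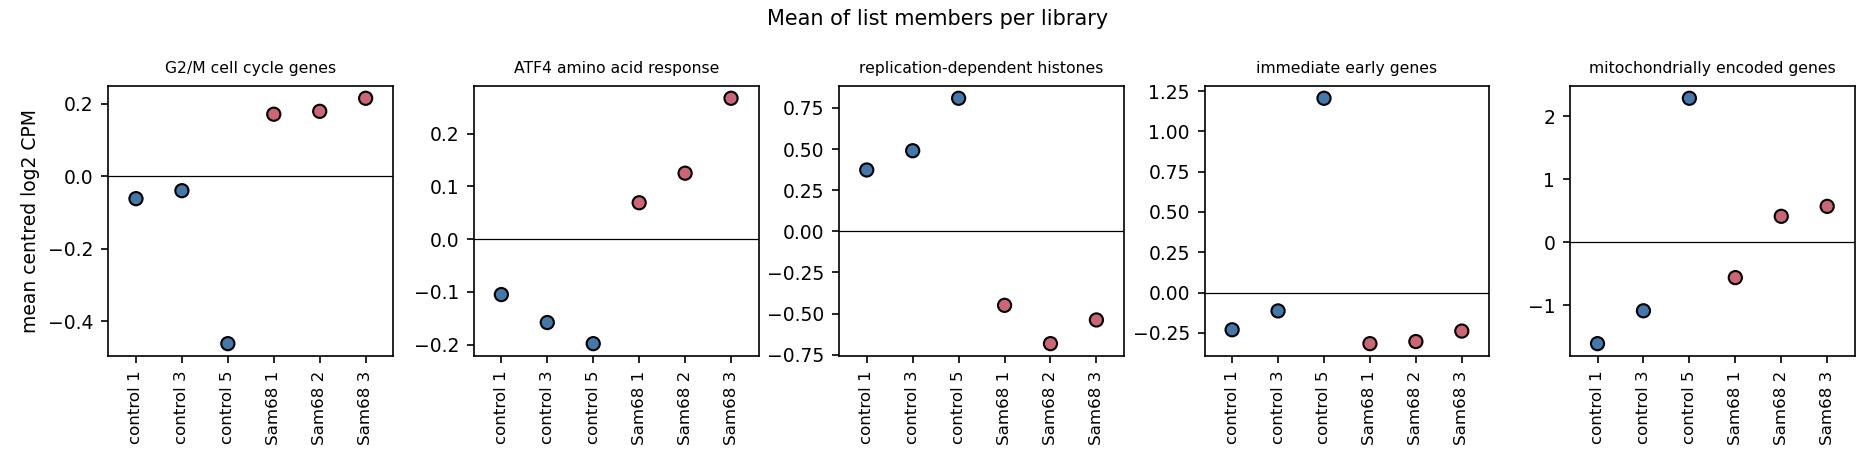
Mean over list members of log2 CPM centred on the 6 libraries (y axis) for 5 lists in each library (x axis). Control replicate 5 lies at 1.21 for immediate early genes and at 2.28 for mitochondrially encoded genes.

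Squamous and epithelial genes moved both ways. Of 33 epithelial junction genes 2 rose, 11 fell and 20 were not called (5 and 12 adjusted over the list alone). The desmosomal cadherins DSC2 and DSG3 fell from 99.6 ± 3.54 to 59.9 ± 1.12 CPM and from 248 ± 15.4 to 158 ± 5.27 CPM (n = 3 each), DSG2 changed by -0.42 in log2, and CDH3, P-cadherin, rose by 0.27. Camera did not call the list (adjusted p = 0.086, and adjusted p = 0.464 with an estimated correlation), and 6, 5 and 5 junction genes fell without Sam68 siRNA replicates 1, 2 and 3 and 6 without control replicate 3. The number that rose was 1 without control replicate 3 and Sam68 siRNA replicates 2 and 3. Of 28 keratinocyte differentiation genes 2 rose, 5 fell and 21 were not called (2 and 5 adjusted over the list alone), among the falls SCEL and IVL, proteins of the cornified envelope, at -1.18 and -1.30 and the plakin PPL at -0.51. Camera gave the keratinocyte differentiation genes an adjusted p of 0.0921, and adjusted p = 0.74 with an estimated correlation. Their adjusted p was 0.00775 and 0.0427 without controls 1 and 3 and 0.735 without control replicate 5, where 4 genes rose and 7 fell; 1 rose without control replicate 1 and 0 without any of the others. Of 21 basal keratinocyte genes 6 rose, 0 fell and 15 were not called (6 rose adjusted over the list alone), KRT5 rising from 2352 ± 13.2 to 2708 ± 2.02 CPM. KRT5 holds GCAGTAC in its coding sequence, and of the 6 basal keratinocyte genes tested without genes holding GCAGTAC or ACTGATT 0 rose (adjusted p = 0.478 for the list by camera). The median log2 fold change of those 6 was 0.086, against 0.095 over all 21, so the lost calls do not show that the heptamers carry the rise. By camera the full list had an adjusted p of 0.086, and adjusted p = 0.664 with an estimated correlation. Without control replicate 5, 11 of these basal keratinocyte genes rose and 1 fell and the list's adjusted p was 0.0014 (adjusted p = 0.448 with an estimated correlation); the highest with 1 library left out was 0.253, without control replicate 1. Without Sam68 siRNA replicates 2 and 3, 2 of the basal keratinocyte genes rose.

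Few markers of other cell types passed the filter on low counts. Of 10 fibroblast markers 4 were tested, of which 0 rose, COL1A1 and FAP fell and 2 were not called (2 fell adjusted over the list alone). FAP, a surface protease, fell from 15.8 ± 1.22 to 8.66 ± 1.97 CPM (n = 3 each), while COL3A1 had at most 6 counts in a library, DCN at most 1 and POSTN 0. The camera test gave an adjusted p of 0.00271, and adjusted p = 0.452 with an estimated correlation. Of 3 tested leukocyte markers 1 rose, 0 fell and 2 were not called (1 rose adjusted over the list alone), and PTPRC had at most 2 counts. LCP1, an actin-bundling protein, stood at 364 ± 18.9 and 415 ± 16.7 CPM (n = 3 each). The LCP1 log2 fold change was 0.19 (adjusted p = 0.0495), and its adjusted p was 0.0985, 0.0541 and 0.0394 without controls 1, 3 and 5 and 0.165, 0.0963 and 0.151 without Sam68 siRNA replicates 1, 2 and 3. Of 3 tested melanocyte and neural markers MAP2, a microtubule-associated protein, fell from 17.6 ± 1.17 to 8.62 ± 0.478 CPM, 0 rose and 2 were not called (1 fell adjusted over the list alone). Camera called neither list (adjusted p = 0.0852 for leukocyte and 0.204 for melanocyte and neural markers, and adjusted p = 0.452 and 0.494 with an estimated correlation).

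Transcripts reported as bound or spliced by Sam68 were compared in total level. Of 11 reported Sam68 target transcripts tested 0 rose, 1 fell and 10 were not called (0 and 1 adjusted over the list alone). Of the reported Sam68 target transcripts 0 were called without controls 1 and 3 or Sam68 siRNA replicates 2 and 3, and 2 rose and 1 fell without control replicate 5. CD44 stood at 1147 ± 151 CPM in controls and 1081 ± 45.5 CPM with the Sam68 siRNA (n = 3 each, edgeR adjusted p = 0.523), CCND1 at 715 ± 17.5 and 639 ± 45.3 CPM (0.0894) and SRSF1 at 216 ± 11.6 and 238 ± 1.54 CPM (0.111). BCL2L1 stood at 239 ± 22.8 and 267 ± 3.11 CPM; the BCL2L1 log2 fold change was 0.16 (adjusted p = 0.129), and 0.24 without control replicate 5 (adjusted p = 0.00741, the lowest with 1 library left out; highest 0.341). The SMN2 log2 fold change, on at most 23 counts in a library, was 1.33 (adjusted p = 0.325), and its adjusted p was 0.0326 without control replicate 5 (highest 0.702). The MTOR log2 fold change was -0.19 (adjusted p = 0.287), and its adjusted p was 0.0369 without Sam68 siRNA replicate 1 (highest 0.618). Camera did not call the list (adjusted p = 0.862, and adjusted p = 0.953 with an estimated correlation), and its direction differed between median, mean and test. These are totals per gene, and splice forms were not analysed here.

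Of the 3 tested STAR family RNA-binding proteins KHDRBS1 fell, QKI rose and SF1 was not called (2 rose and 1 fell adjusted over the list alone), and camera gave an adjusted p of 0.972 (adjusted p = 0.986 with an estimated correlation). QKI rose from 99.5 ± 9.53 to 144 ± 8.28 CPM (n = 3 each; log2 fold change 0.54, adjusted p = 0.000685 by edgeR), and its mRNA holds GCAGTAC in the 3' UTR at chromosome 6, 163573614 to 163573620, and in the coding sequence. SF1 stood at 194 ± 12.7 and 220 ± 2.82 CPM; the SF1 log2 fold change was 0.18 (adjusted p = 0.0542), and 0.23 without control replicate 5 (adjusted p = 0.0114, the lowest with 1 library left out; highest 0.154). Of 20 SR splicing factors and their kinases 3 rose, 2 fell and 15 were not called (3 and 2 adjusted over the list alone), with SRSF8 at -0.51 and the kinase SRPK1 at 0.32; without Sam68 siRNA replicates 2 and 3, 1 rose and 1 fell, and 1 fell without controls 1 and 5. Against other genes the list had an adjusted p of 0.883 by camera, and adjusted p = 0.953 with an estimated correlation. Of 30 genes of mRNA 3-prime end processing and U1 snRNP 8 rose, 0 fell and 22 were not called (8 rose adjusted over the list alone), SNRPA, a protein of the U1 particle that overlaps C19orf54, rising by 0.52. Camera gave this list an adjusted p of 0.0561 (adjusted p = 0.452 with an estimated correlation), and 0.0245 without control replicate 5 (adjusted p = 0.436 with an estimated correlation), where 5 rose; without Sam68 siRNA replicates 1, 2 and 3, 4, 2 and 1 rose, and 3 did without control replicate 3, the setting with the highest adjusted p (0.131).

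Camera called 14 lists, 8 higher and 6 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.452 and 3 had an unadjusted p below 0.05. In the other ways of parting the 6 libraries into 3 and 3 the same camera test called between 6 and 15 lists. Fry called 22.

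The authors' deposited table listed 2036 genes with an FDR below 0.05 that was not below the gene's own p-value, 979 higher and 1057 lower with the Sam68 siRNA. Of the genes so listed in the authors' deposited table, 2004 were tested here and 1803 were changed here too, each with the same sign. A further 555 genes were changed here only, and 32 of those in the authors' deposited table were not tested here. The log2 fold change of KHDRBS1 was -2.83 in the authors' deposited table.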

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

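The test without the genes holding GCAGTAC or ACTGATT was chosen after the result was seen. KHDRBS1 kept its direction and its call in each of 21 alternatives, with log2 fold changes of -2.97 to -2.71, -2.91 to -2.76 with 1 library left out and -2.97 with the replicate block, and a largest adjusted p of 0.000348. Of the other 163 called genes that the naming rule took, none reversed. RLE scaling, upper-quartile scaling, DESeq2 and limma-voom each ended at most 1 of these calls, the block 52, the 1.5-fold test 146, log2(TPM + 1) and log2(RPKM + 1) without a filter 46 and 32, and leaving out controls 1, 3 and 5 and Sam68 siRNA replicates 1, 2 and 3 ended 11, 23, 0, 22, 40 and 35.

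The 2358 changed genes became 1046 with the replicate block, 1112 to 2666 with 1 library left out, 28 (4 higher, 24 lower) in the test against a fold change of 1.5, 1056 and 1355 on log2 TPM and RPKM with a pseudocount of 1 and no filter, and 1418 without the heptamer genes, where fewer genes are tested. The 98 genes changed over 2-fold became 52 with the stricter filter, 25 in the 1.5-fold test, 44 and 42 on log2(TPM + 1) with and without a filter, 19 on log2(RPKM + 1) with and without a filter, 42 on log2(RPKM + 0.1), and 79 to 111 with 1 library left out. Pseudocounts shrink the fold changes of low genes and the stricter filter tests fewer genes. In the block, control replicate 5 and Sam68 siRNA replicate 2 share their number with no library of the other group. The group effect there rests on replicates 1 and 3 of each group, so on fewer libraries than in the main test. For the other moves the cause was not tested. Higher genes made up 48.9% of calls, and 47.0% to 54.0% in the alternatives other than the 1.5-fold test (14.3%).

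The 14 lists became 22 with DESeq2, 22 with fry (11 of the 14 kept, without G2/M, G1/S and immediate early genes), 0 with an estimated correlation, and 13 to 17 with 1 library left out. Each of the 14 kept the direction given by the list test throughout. The median log2 fold change of immediate early genes, -0.46 over all 6 libraries, was 0.02 without control replicate 5. For DESeq2 the list test differed too, as cameraPR, with the preset correlation of 0.01, was run on its test statistics. The cause of these moves was not tested. Without control replicate 5 fry called G2/M, G1/S and immediate early genes (adjusted p = 0.00994, 0.0319 and 0.0414) but not cytosolic ribosomal proteins (0.0711). The replicate numbers 1 and 3 occur in both groups, and same-numbered libraries did not deviate together (r = -0.066 and 0.077). Those deviations are from means of 3 libraries, with control replicate 5 apart. They cannot settle whether a shared number marks a pair. With that block 15 lists passed, 12 of the 14 among them; cholesterol biosynthesis (adjusted p = 0.0622) and immediate early genes (0.389) did not. Without genes holding GCAGTAC or ACTGATT 18 lists passed, all 14 among them, and those gained were epithelial junction genes (adjusted p = 0.0162), TGF-beta/SMAD targets (0.0162), EMT mesenchymal genes (0.0425) and mRNA 3-prime end processing and U1 snRNP (0.0451), each with adjusted p = 0.374 with an estimated correlation. List tests were not run without robust estimation or for the 1.5-fold test.

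Log2 fold changes of 3 uncalled Sam68 targets changed sign. CD44 was at 0.027 with the block and -0.18 to 0.0063 with 1 library left out, SGCE at -0.11 and -0.077 to 0.14, and EPB41 at -0.11 to 0.045 with 1 library left out. With 3 libraries per group, 28% of the smallest simulated changes were called, so small changes may be missed among the genes not called. The number of genes called depended on which library was left out, from 1112 without Sam68 siRNA replicate 2 to 2666 without control replicate 5.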

Other observations

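Among the tests below, those of the sequence matches of both heptamers and of the G2/M count without control replicate 5 were chosen after the result was seen.

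Genes of the EGF receptor family and its ligands included 4 that fell of 13 tested, with 1 that rose and 8 not called (2 rose and 5 fell adjusted over the list alone). The ligand EREG fell from 147 ± 8.14 to 92.5 ± 7.51 CPM (n = 3 each), and TGFA, the receptor ERBB3 and the feedback inhibitor ERRFI1 changed by -0.62, -0.60 and -0.43 in log2; camera gave an adjusted p of 0.169 (adjusted p = 0.464 with an estimated correlation), and 0 rose without Sam68 siRNA replicate 1 and 2 without control replicate 5. These 4 genes hold ACTGATT in the 3' UTR, and of the 8 members tested without genes holding GCAGTAC or ACTGATT 1 rose and 0 fell (adjusted p = 0.6 by camera, in the other direction). That step left out all 4 genes that fell, so its count of 0 was fixed in advance. Neither the count nor the other direction shows that the heptamer carries the falls. Of 8 CDK inhibitors 1 rose, 2 fell and 5 were not called (1 and 2 adjusted over the list alone). CDKN2B fell from 115 ± 9.91 to 65.8 ± 7.66 CPM, CDKN1A changed by -0.40, and CDKN3, a phosphatase, rose by 0.65; camera gave 0.862 (adjusted p = 0.953 with an estimated correlation), with a median and a mean that differ in sign. Of 28 p53 target genes 4 rose, 5 fell and 19 were not called (5 and 7 adjusted over the list alone), CCNG1 and PLK2 falling by log2 changes of -0.68 and -0.73 and GDF15 rising by 0.34. The p53 list had an adjusted p of 0.662 by camera (adjusted p = 0.74 with an estimated correlation), also with median and mean that differ in sign; 1 gene rose without controls 1 and 5 and without Sam68 siRNA replicates 2 and 3.

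In the TGF-beta/SMAD targets 3 of 21 rose, 5 fell and 13 were not called (3 and 5 adjusted over the list alone), ID4, an inhibitor of helix-loop-helix factors, falling from 22.9 ± 5.59 to 9.34 ± 1.17 CPM (n = 3 each; camera adjusted p = 0.11, and adjusted p = 0.494 with an estimated correlation). The number that rose was 1 without Sam68 siRNA replicates 1 and 2, and the number that fell was 3 without Sam68 siRNA replicates 2 and 3. Of 13 integrins 2 rose, 3 fell and 8 were not called (2 and 3 adjusted over the list alone), ITGB2, a leukocyte integrin subunit, falling from 43.4 ± 1.37 to 24.1 ± 0.399 CPM (adjusted p = 0.306 by camera, and adjusted p = 0.494 with an estimated correlation). None of the integrins rose without control replicate 3 or any single Sam68 siRNA library, 1 rose without control replicate 1, and 1 fell without Sam68 siRNA replicate 2; 3 rose and 5 fell without control replicate 5. Of 23 EMT mesenchymal genes 4 rose, 5 fell and 14 were not called (4 and 5 adjusted over the list alone), COL6A1 rising by 0.29 (adjusted p = 0.46 by camera, and adjusted p = 0.74 with an estimated correlation); without Sam68 siRNA replicates 2 and 3, 2 and 3 of them rose and 2 and 2 fell. Of 24 extracellular matrix proteases and inhibitors 5 rose, 5 fell and 14 were not called (5 and 5 adjusted over the list alone), with PLAT and TIMP3 at 0.36 and 0.35 and TIMP2 and MMP2 at -0.54 and -0.31 (adjusted p = 0.88 by camera, and adjusted p = 0.953 with an estimated correlation). Of the proteases 3, 2 and 2 rose without Sam68 siRNA replicates 1, 2 and 3 and 3 without control replicate 3, and 2 and 3 fell without Sam68 siRNA replicates 2 and 3.

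Of 46 interferon-stimulated genes 6 rose, 8 fell and 32 were not called (6 and 8 adjusted over the list alone), CXCL11 and OAS3 rising by 0.65 and 0.43 (adjusted p = 0.862 by camera, and adjusted p = 0.953 with an estimated correlation); 4 fell without Sam68 siRNA replicate 2, 5 without Sam68 siRNA replicate 3 and 5 without control replicate 3. Of 17 genes of MHC class I antigen presentation 0 rose, 4 fell and 13 were not called (4 fell adjusted over the list alone; camera adjusted p = 0.107, and adjusted p = 0.494 with an estimated correlation), and 0 fell without Sam68 siRNA replicate 1, 1 without Sam68 siRNA replicate 3 and 7 without control replicate 5. Of 35 NF-kB inflammatory targets 1 rose, 5 fell and 29 were not called (1 and 5 adjusted over the list alone), BIRC3 falling from 90.6 ± 6.97 to 58.7 ± 5.53 CPM (n = 3 each). The NF-kB list had an adjusted p of 0.108 by camera (adjusted p = 0.805 with an estimated correlation), 0.00716 and 0.027 without controls 1 and 3, and 0.767 in the other direction without control replicate 5, where 6 rose and 5 fell; 3 fell without Sam68 siRNA replicates 1 and 2, and 0 rose without these or controls 1 and 3. Of 18 genes of ERK pathway output 4 rose, 0 fell and 14 were not called (5 rose adjusted over the list alone), ETV5 rising by 0.47 (adjusted p = 0.108 by camera, and adjusted p = 0.74 with an estimated correlation). Without control replicate 5, 10 of the ERK pathway output genes rose and the adjusted p was 0.00109 (adjusted p = 0.448 with an estimated correlation; with the preset correlation the highest with 1 library left out was 0.396, without control replicate 1); 2 rose without control replicate 1 and without Sam68 siRNA replicates 1 and 2, and 1 without control replicate 3 and Sam68 siRNA replicate 3.

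Of 13 Notch targets 2 rose, 4 fell and 7 were not called (2 and 7 adjusted over the list alone), with a camera adjusted p of 0.0721 (adjusted p = 0.452 with an estimated correlation). The Notch targets had 0.0431 and 0.0168 without controls 1 and 3, 0.0357, 0.0408 and 0.049 without Sam68 siRNA replicates 1, 2 and 3, and 0.171 without control replicate 5; 1 fell without control replicate 3 and Sam68 siRNA replicate 2, and 2 without Sam68 siRNA replicate 3, where 0 rose; 1 rose without any other single library but control replicate 5. Of 16 BCL2 family genes 0 rose, 2 fell and 14 were not called (2 fell adjusted over the list alone; camera adjusted p = 0.108, and adjusted p = 0.452 with an estimated correlation), and 1 fell without control replicate 3 or any single Sam68 siRNA library, and 1 rose without control replicate 5. Of 12 Wnt/beta-catenin targets 2 rose, 2 fell, among them the secreted antagonist DKK1 at -0.66, and 8 were not called (2 and 2 adjusted over the list alone; camera adjusted p = 0.528, and adjusted p = 0.69 with an estimated correlation); without each Sam68 siRNA library 1 rose and 1 fell, and 1 fell without control replicate 3. Of 37 genes of hypoxia and glycolysis 6 rose, 2 fell and 29 were not called (7 and 4 adjusted over the list alone), VEGFA and P4HA1 rising by 0.50 and 0.48 (camera adjusted p = 0.406, and adjusted p = 0.718 with an estimated correlation), and 3 rose without control replicate 3 or any single Sam68 siRNA library, where 0, 1, 0 and 0 fell in that order. Of 24 ER chaperones and unfolded protein response genes 2 rose, 3 fell and 19 were not called (2 and 3 adjusted over the list alone), HYOU1 rising by 0.40 (camera adjusted p = 0.296, and adjusted p = 0.551 with an estimated correlation); without each Sam68 siRNA library 1 rose and 1 fell, and 1 rose without control replicate 1.

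Of 13 stem and squamous identity genes 4 rose, 0 fell and 9 were not called (5 rose adjusted over the list alone; camera adjusted p = 0.31, and adjusted p = 0.664 with an estimated correlation), with a median of -0.03 against a higher mean, and 1 rose without Sam68 siRNA replicates 2 and 3. Of 12 genes of siRNA and microRNA machinery 1 rose, TNRC6A by 0.40, 2 fell, AGO3 among them at -0.50, and 9 were not called (3 and 2 adjusted over the list alone; camera adjusted p = 0.753, and adjusted p = 0.953 with an estimated correlation); 1 fell without control replicate 3 and without Sam68 siRNA replicates 2 and 3, and 2 rose without control replicate 5. Of 63 nuclear oxidative phosphorylation subunits 3 rose, 1 fell and 59 were not called (0 adjusted over the list alone; camera adjusted p = 0.972, and adjusted p = 0.986 with an estimated correlation), and 0 were called without Sam68 siRNA replicates 2 and 3, 1 rose without Sam68 siRNA replicate 1 and control replicate 1, 0 fell without control replicate 3 and Sam68 siRNA replicate 1, and 2 fell without control replicate 5. Of 14 heat shock response genes 1 rose, 0 fell and 13 were not called (2 and 2 adjusted over the list alone; camera adjusted p = 0.862, and adjusted p = 0.953 with an estimated correlation), and 0 rose without Sam68 siRNA replicate 2, 2 rose without control replicate 1 and 1 fell without Sam68 siRNA replicate 1. Of 20 housekeeping genes 0 rose, 1 fell and 19 were not called (0 adjusted over the list alone; camera adjusted p = 0.686, and adjusted p = 0.935 with an estimated correlation), and 0 fell without Sam68 siRNA replicates 2 and 3, 2 without control replicate 1 and 3 without control replicate 5.

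Control replicate 5 stood apart from controls 1 and 3. Its mitochondrially encoded genes lay at 2.28, as a mean log2 deviation from the 6 libraries, against -1.61 and -1.09, its keratinocyte differentiation genes at 0.529 against -0.099 and 0.004, and its NF-kB inflammatory targets at 0.468 against -0.154 and -0.064. Of 13 mitochondrially encoded genes 0 were called (0 adjusted over the list alone), with a median of -0.73 and a camera adjusted p of 0.754 in the other direction (adjusted p = 0.953 with an estimated correlation). Without control replicate 5 the mitochondrially encoded genes had a median of 1.60 and an adjusted p of 4.25e-06 (adjusted p = 0.45 with an estimated correlation), with 0 genes called.

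Genes higher with the Sam68 siRNA carried GCAGTAC in their 3' UTRs more often than others, and it had the highest adjusted z of 15710 heptamers, 14.1, against 5.83 as the highest of 1000 permutations. The highest z of 544 other heptamers of the same composition was 3.51, below that permuted value, so composition alone gave no such z. Their distance from GCAGTAC is no test. GCAGTAC was singled out after the data were seen. The next highest z of all heptamers was 8.18, for CAGTACA, which overlaps GCAGTAC in sequence. Control replicate 5 as the sole source is argued against, since z was 13.4 without it. Silencing of seed-matched mRNAs by the control siRNA, which would make them higher in the cells given the other siRNA, is a candidate explanation. The rank of GCAGTAC is no independent support for it, as the heptamer was chosen after the result was seen. The coding sequences gave a z of 11.5. Whether the effect grows with the number of sites cannot be told apart from no growth, as medians of 34 genes with 2 or more sites and 526 with 1 differed by 0.0246 (95% bootstrap interval -0.0508 to 0.216). The siRNA sequences are not given in the sources used here, and since each group received its own siRNA, an effect of Sam68 loss on these mRNAs stays open and untested.

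Genes lower with the Sam68 siRNA carried ACTGATT in the 3' UTR more often than others, though 937 that fell lacked it there and 248 held it. It had the lowest adjusted z in 3' UTRs, -7.00, against -5.86 as the lowest of the permutations. The adjusted log2 difference was -0.0606, and the KHDRBS1 mRNA holds 1 site. The lowest z of 409 other heptamers of the composition of ACTGATT was -3.04, above that permuted value, so composition alone gave no such z. Their distance from ACTGATT is no test, as ACTGATT was singled out after the data were seen. The next lowest z of all heptamers was -5.72, for CTGATTA, which overlaps ACTGATT in sequence. Without control replicate 5 the z of ACTGATT was -7.13, against -6.26 as the lowest permuted there. This argues against that library as the sole source. Silencing of seed-matched mRNAs by the Sam68 siRNA is a candidate explanation, though 13.8% of searched genes hold the heptamer in the 3' UTR, so the site in KHDRBS1 carries little weight. In coding sequences its z was -2.23. An effect of Sam68 loss stays open and untested, for the reason given above.

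Cell cycle lists were higher with the Sam68 siRNA by camera with the preset correlation, but not called with an estimated one (adjusted p = 0.494 with an estimated correlation for G2/M and for G1/S). Fry called neither over all 6 libraries (adjusted p = 0.0931 and 0.0504) and both without control replicate 5 (0.00994 and 0.0319). Control replicate 5 was the lowest library for both cell cycle lists. That library as the sole source is argued against, since 27 G2/M genes rose without it, against 25 with it, though their median log2 fold change was 0.25 without it and 0.38 with it, so part of the size may rest on that library. Direct silencing of list members through GCAGTAC is argued against for the 48 of 54 G2/M genes without it in the 3' UTR or coding sequence searched. Shorter or shifted matches such as CAGTACA, and other transcripts, were not counted as sites, so silencing through those is not addressed. The median log2 fold change of the 48 genes was 0.363 over all 6 libraries (95% bootstrap interval over genes 0.300 to 0.406). That interval treats genes as independent, though the estimated correlation over the whole list was 0.785, and does not measure the spread between libraries. Indirect effects of either siRNA on growth, and an effect of Sam68 loss, stay open and untested.

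The 6 libraries can be parted into 3 and 3 in 10 ways, too few for a share under 0.05. The real grouping gave 2358 changed genes, 98 over 2-fold and 14 lists, and the highest of the other groupings gave 2, 2 and 15. As many changed genes came from 1 of the 10 groupings, as many over 2-fold from 1 and as many lists from 2, the real one included; the other was control replicate 1 with Sam68 siRNA replicates 1 and 2 against the rest.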
